A study of Homo sapiens with 8 samples.

How the data were processed

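Poly(A) RNA of an hTERT dermal microvascular endothelial line was sequenced in 8 libraries, 4 labelled wild type and 4 labelled SMAD6 knockout. Per the labels' protocols, total RNA was extracted on a Maxwell RSC instrument and libraries were made with a TruSeq stranded mRNA kit. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0 and StringTie 2.1.3b were used with build GRCh37; whether the strand was used in counting is not given in the sources used here. The deposited table holds, per the file headers, 1 row for each of 24253 genes with raw read counts, FPKM and TPM for each library. The authors also deposited log2 values per library and log2 group means, a fold change with its score statistic and standard error on the log2 scale, a mean normalised signal, and unadjusted and adjusted p-values, per the file headers. The log2 values per library and the FPKM values were not used.

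Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14960 genes holding 99.97% of all reads, scaled by TMM and tested with the quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit held the group alone. A gene with no read in a group was given a fold bound from a floor of 3 counts per library, and a group total of 1 to 3 reads a ratio with an exact 95% Clopper-Pearson interval; floors and intervals cover counting error only. CPM values are TMM-normalised. Gene lists fixed in advance, 33 in number, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists with at least 5 tested genes, then with the correlation estimated for each list, and with fry. Of 11 calls with the preset correlation, 0 held with an estimated one, where 5 lists had an unadjusted p under 0.05, and fry called 24.

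Genes were named by a rule set before the data were examined, as were the lists, the gene and list tests and most of the other settings tried. Some of the tests of explanations were chosen after the result was seen. The rule took SMAD6, the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between groups and an average log2 CPM of at least 3, up to 2 rises and 2 falls past the threshold per list, and a fixed set of BMP, ERK, proliferation and endothelial genes; XIST, Y-linked genes, clone names and microRNA genes were left out. Of the genes that the rule gives, 2 are not reported here and all others are named. MTAP, KLHL9, DMRTA1 and CDKN2B-AS1, the ends of the chromosome 17 block and the fibroblast genes COL3A1, LUM and DCN were added after their values were seen. Gene order came from the RefSeq table of GRCh38.p14, which differs from the build of the counts, so no coordinate is given; 24216 of 24253 gene identifiers matched. The block on chromosome 17 was placed by a single change point in the log2 fold changes of tested genes above an average log2 CPM of 2, in order.

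The steps were tested on simulated counts drawn for this comparison, with 14664 genes tested. Of 100 genes changed 1.5-fold, 77.0% were recovered, of 100 changed 2-fold 98.0%, and 9 of 14438 unchanged genes were called. These 9 made 4.31% of the calls. The simulation changed few genes and drew each library independently, so it did not test the steps under a wide change or under paired replicates. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.43 or more in each of the 12 pairs, so none was merged. The labels give replicates 1 to 4 in both groups. Same-numbered libraries deviated together from their group means, with correlations across genes of 0.20, 0.20, 0.13 and 0.23. The numbers were therefore taken to pair the samples. A principal component holding 4.96% of the variance parted replicates 1 and 2 from 3 and 4 in both groups. Chi-square per degree of freedom was 4.43 and 13.2 within these sets in wild type, and 15.6 and 19.4 in the libraries labelled knockout. Across the sets of a group it was 29.99 to 48.52. The 4 libraries of a group thus lay in 2 sets and may not be independent. The main fit used neither the pairing nor these sets and treated the 4 libraries of a group as independent, as did each SD. An alternative fit with a replicate block used the pairing. A check for mixed-up samples found 0 libraries unlike the rest of their own group and 4 of the 8 libraries unlike the other 4.

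Alternatives were other scaling factors, no filter or a stricter one, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, a minimum 1.2-fold change, and leaving out each library. Added after the data were seen were fits without the chromosome 17 block, with replicates 1 and 2 alone and with replicates 3 and 4 alone. Tests on summed against unsummed rows were not run, since each gene has 1 row. Of the genes in the authors' deposited table, 7596 have an adjusted p under 0.05, of which 7048 were also called here with edgeR, each in the same direction. In the authors' deposited table SMAD6 is 1.82-fold higher.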

Results

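RNA was sequenced from a human dermal microvascular endothelial line, kept growing by added telomerase (hTERT) and cultured untreated in endothelial growth medium. The 8 libraries fall into 4 labelled wild type and 4 labelled SMAD6 knockout. SMAD6 is an inhibitory SMAD that restrains bone morphogenetic protein (BMP) signalling. Total counts per library ranged from 50128402 to 58288805, with 57361710 ± 737762 (SD, n = 4) in wild type and 52469894 ± 2603872 (SD, n = 4) in the libraries labelled knockout. Mitochondrial genes took 4.68% ± 0.0630 (SD, n = 4) and 5.56% ± 0.378 (SD, n = 4) of the counts. Across tested genes, log2 CPM values correlated at 0.990 to 0.995 between libraries of a group and at 0.930 to 0.936 between groups; genes are not independent replicates. The labels do not say that replicates came from separate cultures, so each p measures only the spread between these samples, which may be technical.

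SMAD6 (Entrez Gene 4091) was not lower in the libraries labelled knockout. Its reads numbered 401, 410, 478 and 518 in wild-type replicates 1 to 4 and 601, 659, 1032 and 694 in replicates 1 to 4 labelled knockout. The normalised level was 7.85 ± 0.949 CPM (SD, n = 4) in wild type and 14.4 ± 4.21 CPM (SD, n = 4) in the other group, a log2 fold change of 0.87 (SE 0.17, edgeR adjusted p = 0.00153). All 4 libraries labelled knockout lay above all 4 wild-type libraries, and the groups did not overlap in 45.2% of all tested genes. The transcript level thus gave no sign of a loss of SMAD6, and counts per gene cannot show a small change within a coding sequence. Every direction given here is that of the libraries labelled knockout against those labelled wild type. The labels of these 4 libraries also carry the name GFP, which those of the wild-type libraries do not, so the marker and the knockout cannot be separated.

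**Figure D1:**
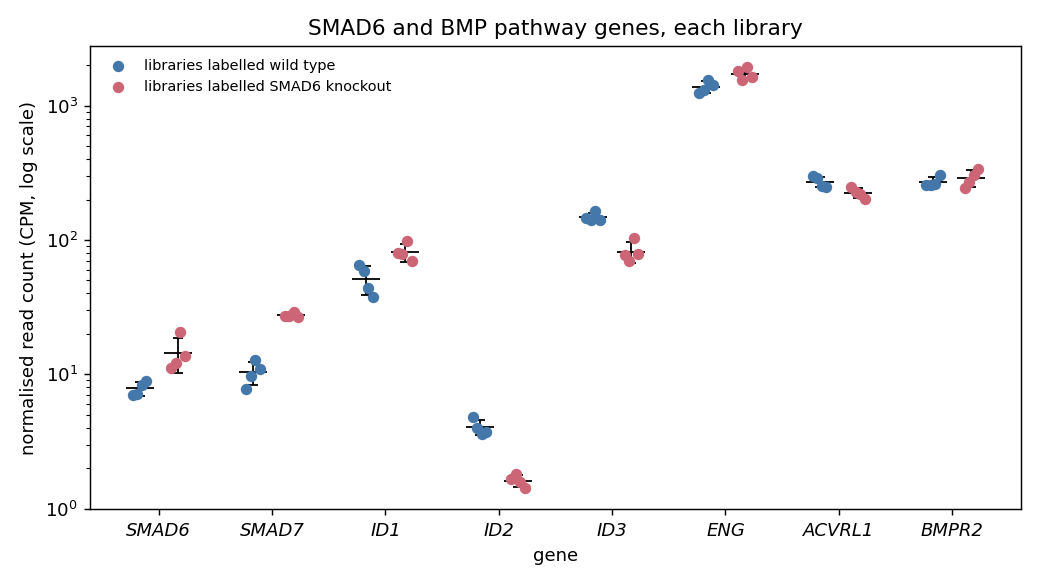
Normalised read counts (CPM, log axis) of SMAD6 and 7 BMP pathway genes in each of the 8 libraries, blue for wild type and red for the libraries labelled SMAD6 knockout; black bars give the mean and SD of 4 libraries. SMAD6 averaged 7.85 CPM in wild type and 14.4 CPM in the libraries labelled knockout, while ID2 averaged 4.04 and 1.62 CPM.

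The groups differed widely in expression. Of 14960 genes tested, 7228 passed an edgeR adjusted p of 0.05, with 3452 higher and 3776 lower in the libraries labelled knockout. Among them 2069 had changed at least 2-fold, 962 upwards and 1107 downwards. Against a minimum 1.2-fold change 4072 genes passed, 1901 higher and 2171 lower. With limma on log2(TPM + 1), where 13209 genes were tested, 2462 were higher and 3746 lower, so 39.7% of the changed genes were higher against 47.8% on counts, and 1007 had changed at least 2-fold. On log2(TPM + 0.1) the counts were 2458, 3735 and 1316. Among genes past the threshold with an average log2 CPM of at least 3 and no overlap between groups, the 12 highest rises started from low levels in wild type. LPL, lipoprotein lipase, had 3 reads over the 4 wild-type libraries and 8754 over the other 4, a ratio of 3190.1 with a 95% counting interval of 1091 to 15472. SCUBE1 went from 0.152 ± 0.0591 to 152 ± 15.6 CPM (SD, n = 4), DNASE1L3, a secreted nuclease, from 1.98 ± 0.362 to 200.2 ± 34.0 CPM, FAM107A from 1.84 ± 0.295 to 165 ± 11.5 CPM and MCTP1 from 2.56 ± 0.406 to 157 ± 20.3 CPM. ATP6V0A4, DCLK1, PLCB4 and MIR217HG, the host transcript of a microRNA, each had 4 to 8 reads over the wild-type libraries and 3367 to 5474 over the others. CMKLR1, the chemerin receptor, EPN3, which lies in the chromosome 17 block, and FAM174B rose by 7.72, 6.42 and 5.93 on the log2 scale. TERT, whose reads can come from the telomerase transgene, rose from 1518 ± 61.2 to 5165 ± 649 CPM (SD, n = 4), a log2 fold change of 1.77.

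Several abundant transcripts of wild type had no read in any library labelled knockout. COL1A2, a chain of type I collagen, stood at 84.0 ± 21.5 CPM (SD, n = 4) in wild type and was at least 1466-fold lower, with a floor of 3 counts per library. APCDD1L, from 70.6 ± 4.98 CPM, was at least 1233-fold lower, the desmosomal cadherin DSG2, from 36.6 ± 1.77 CPM, at least 638-fold, and the neurofilament chain NEFH, from 22.1 ± 1.68 CPM, at least 387-fold. PTK7, a receptor-like pseudokinase, had 4861 reads in wild type and 2 in the other group, a ratio of 2223 with a 95% counting interval of 615 to 18363. COL6A2 fell from 70.0 ± 2.23 to 0.0446 ± 0.0521 CPM, FLT4, the VEGF-C receptor, from 31.9 ± 1.94 to 0.0446 ± 0.0521 CPM and EMILIN1, an elastic fibre protein, from 50.9 ± 1.24 to 0.124 ± 0.111 CPM (SD, n = 4). The log2 fold changes of ADAM23 and SPECC1 were -6.93 and -6.76, and EFNB2 and FBLN5 fell from 37.8 ± 1.12 to 0.270 ± 0.123 CPM and from 24.2 ± 5.32 to 0.186 ± 0.0763 CPM. In all, 49 genes with a mean of 1 CPM or more in wild type had no read in the 4 libraries labelled knockout, and 6 genes showed the opposite.

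A run of neighbouring genes on chromosome 17 was higher in every library labelled knockout. Genes above an average log2 CPM of 2 were placed in order, with METRNL as the last. From WSB1 to METRNL, 501 such genes had a median log2 fold change of 1.00. Of them 467 rose and 11 fell past the edgeR threshold. The medians in the 4 libraries were 1.01, 0.97, 1.03 and 0.98. The other 198 genes of chromosome 17 at that level had a median of -0.00318, and the medians of the other autosomes ran from -0.11 to 0.05. With tested genes of any level counted, this block held 643 genes, of which 553 rose, out of 3452 rises in all, and 28 fell. Apart from its bounds, the genes named in the text that lie in it are EPN3, TMEM100, ETV4, CDC6, TOP2A, BIRC5, FDXR, ICAM2, RFNG, GJC1, KRT10, KRT15, CCL2 and CSF3. The bounds of the block were set after its values were seen.

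**Figure D2:**
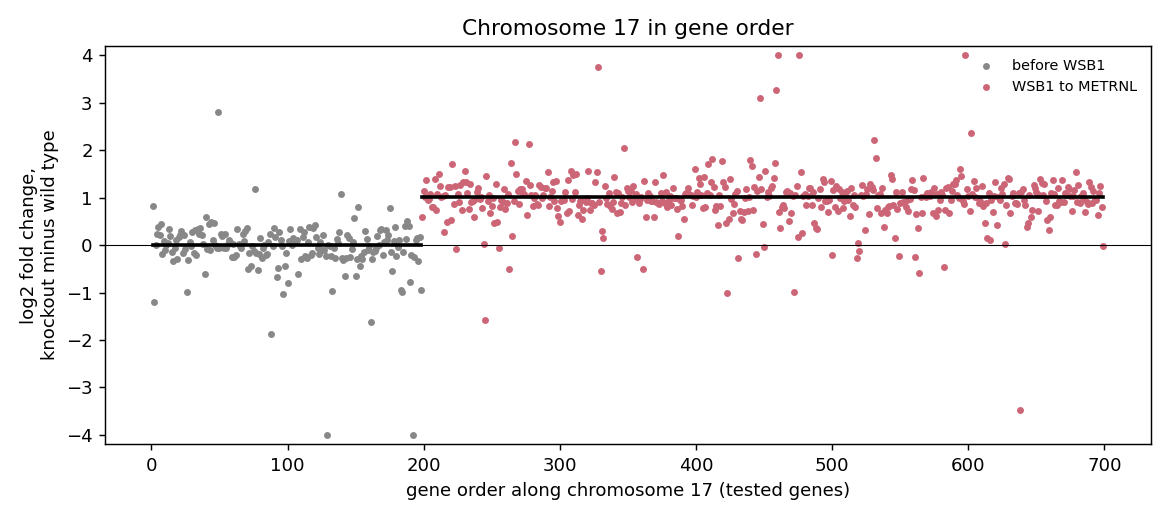
Log2 fold change (libraries labelled SMAD6 knockout minus wild type) of the tested genes of chromosome 17 above an average log2 CPM of 2. Genes are in their order along it, with 5 points beyond 4 drawn at the edge. Red marks the run from WSB1 to METRNL and black lines the medians. The run has a median of 1.00 and the genes before it one of -0.00318.

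SMAD6 restrains BMP signalling, and the target genes of that pathway moved both ways. SMAD7, the other inhibitory SMAD, rose from 10.3 ± 2.04 to 27.5 ± 1.21 CPM (SD, n = 4), a log2 fold change of 1.41. The direct BMP targets of the ID family split: ID1 rose by 0.66 (SE 0.16) on the log2 scale, while ID2 fell by 1.32 (SE 0.14) and ID3 fell by 0.85 (SE 0.11). TMEM100, a gene induced by ACVRL1 signalling that lies in the chromosome 17 block, rose by 5.06 (SE 0.20) on the log2 scale, and the BMP antagonist GREM1 fell from 51.2 ± 6.31 to 2.30 ± 0.266 CPM (SD, n = 4). HEY1, a target shared with NOTCH, fell by 1.94 (SE 0.28). Of the 14 BMP-SMAD target genes tested, 4 rose, 7 fell and 3 did not pass the edgeR test. Over all tested genes 48.3% passed it, with 3452 higher and 3776 lower. Mixed rises and falls within a list are therefore not by themselves particular to its pathway. As a set the list was not called by camera (adjusted p = 0.266, and adjusted p = 0.503 with an estimated correlation). Camera called 11 of the 29 lists tested and none of them with an estimated correlation, where 5 had an unadjusted p under 0.05, and 3 of the 35 splits of the libraries into 4 and 4 gave as many list calls.

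The series title names hereditary hemorrhagic telangiectasia, in which ENG, ACVRL1 and SMAD4 are mutated. ENG, the endoglin co-receptor, was 1380.4 ± 138 CPM in wild type and 1733 ± 177 CPM in the libraries labelled knockout (SD, n = 4), a log2 fold change of 0.33 (SE 0.09, edgeR adjusted p = 0.00892). ACVRL1, the ALK1 receptor, went from 271 ± 24.9 to 224 ± 19.9 CPM (SD, n = 4), a log2 fold change of -0.27 (SE 0.08, edgeR adjusted p = 0.0148). SMAD4 and the BMP receptor BMPR2 did not pass, with log2 fold changes of -0.10 (SE 0.07) and 0.10 (SE 0.10). The larger changes lay elsewhere in the family: BMPR1A fell from 10.3 ± 1.33 to 0.587 ± 0.219 CPM and the ligand BMP2 from 7.06 ± 3.26 to 0.247 ± 0.216 CPM, while BMP4 rose by 1.13 and SMAD9 by 0.99 on the log2 scale. Among 23 receptors, ligands and SMADs tested, 3 rose and 10 fell, or 4 and 11 adjusted over the list alone, and camera gave no call (adjusted p = 0.118). The ENG and ACVRL1 calls ended when tested against a minimum 1.2-fold change, with edgeR adjusted p of 0.249 and 0.490. The ENG call also ended with replicates 3 and 4 alone, a fit chosen after the data were seen, where its log2 fold change was 0.27 (edgeR adjusted p = 0.0537).

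The series title names ERK stimulation, and genes that ERK signalling induces went in both directions. SPRY4, a feedback inhibitor of receptor tyrosine kinases, rose from 25.9 ± 3.91 to 55.5 ± 16.4 CPM (SD, n = 4), a log2 fold change of 1.10, and the transcription factor ETV4, in the chromosome 17 block, rose by 0.93 (SE 0.14). SPRED2, another inhibitor of the pathway, fell by 1.19 (SE 0.10) and the growth factor HBEGF fell by 0.86 (SE 0.26). DUSP6, the ERK phosphatase, was 138 ± 27.7 CPM in wild type and 154 ± 36.8 CPM in the other group, with a log2 fold change of 0.16 (SE 0.17, edgeR adjusted p = 0.475, and 0.0180 with the replicate block). CCND1, cyclin D1, fell by 0.37 (SE 0.14, edgeR adjusted p = 0.0448). Of 22 ERK output genes tested, 6 rose, 7 fell and 9 did not pass, and camera gave no call (adjusted p = 0.906, and adjusted p = 0.959 with an estimated correlation), pointing down, but up without replicate 3 or 4 labelled knockout (adjusted p = 0.931 and 0.940). Of 13 immediate-early genes, 5 rose and 3 fell, led by the nuclear receptors NR4A1 and NR4A2 with rises of 1.70 and 1.44 on the log2 scale, and camera gave no call (adjusted p = 0.533). KLF6, a zinc finger factor, fell by 0.47, and ATF3, a stress-induced factor, fell by 0.49 (edgeR adjusted p = 0.0389). The CCND1 call was lost without wild type replicate 1 or 2 (edgeR adjusted p = 0.105 and 0.106) and without replicate 3 or 4 labelled knockout (0.119 and 0.112), with no low-count filter (0.0798) and against a minimum 1.2-fold change (0.253). The ATF3 call was lost without wild type replicate 1, 3 or 4 (edgeR adjusted p = 0.0628, 0.119 and 0.0854) and without replicate 1, 2 or 3 labelled knockout (0.0868, 0.0981 and 0.0726). Limma voom (adjusted p = 0.0677), no low-count filter (0.0711), a minimum 1.2-fold change (0.147) and replicates 1 and 2 alone (0.132, chosen after the data were seen) ended it too.

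**Figure D3:**
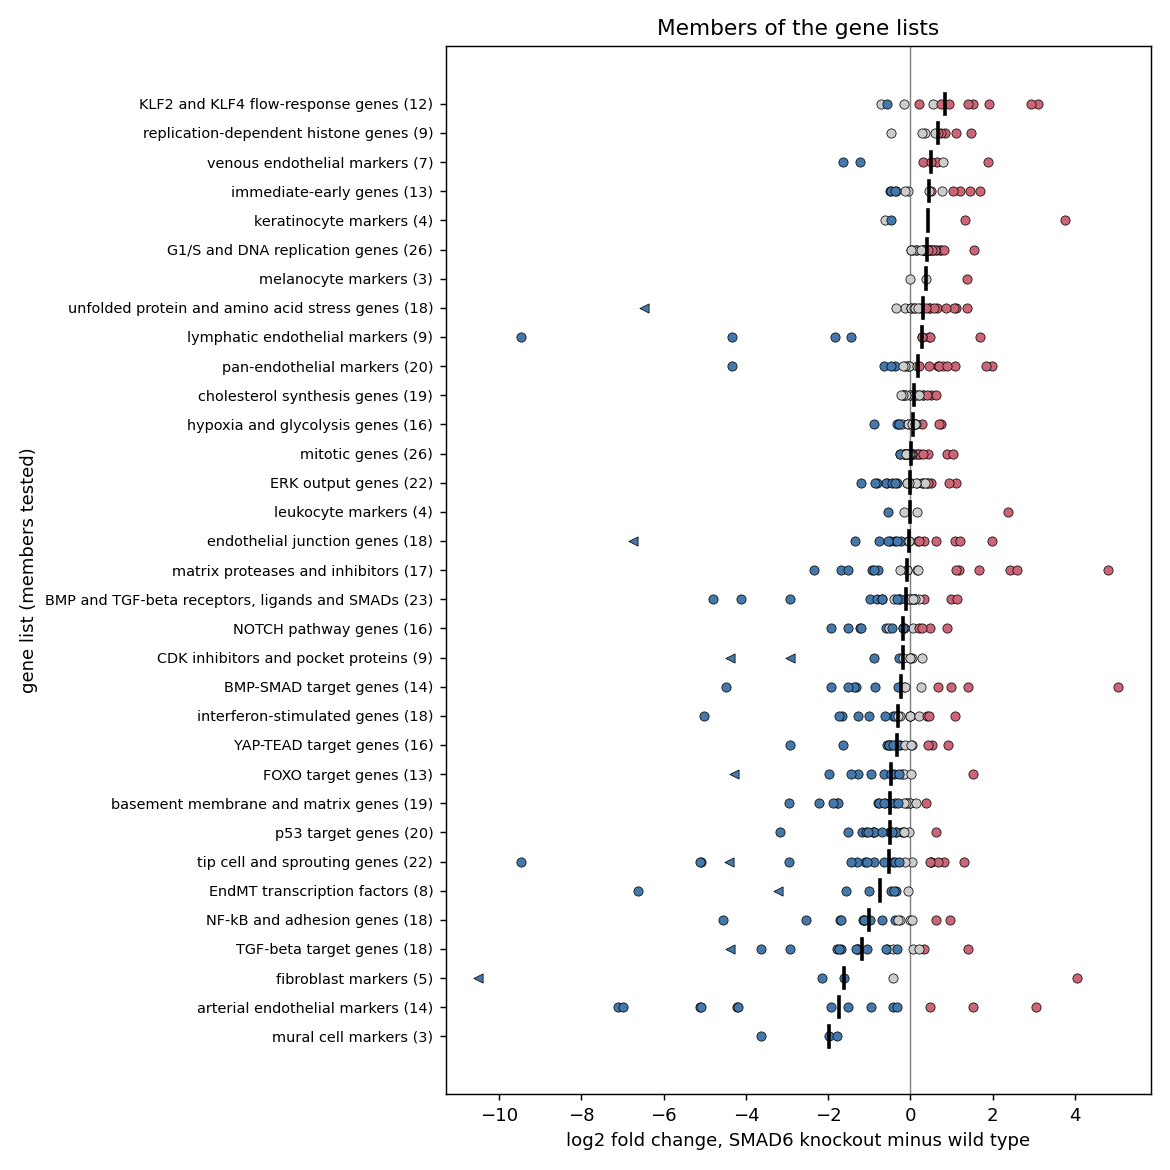
Log2 fold change (libraries labelled SMAD6 knockout minus wild type) of each tested member of the gene lists, 1 row per list with the members tested in brackets; red and blue points rose and fell past an edgeR adjusted p of 0.05, grey points did not pass, triangles are lower bounds on a fall for genes with no read in 1 group, and black bars are medians. G1/S genes had a median of 0.41, mitotic genes of 0.01, ERK output genes of -0.00447 and TGF-beta targets of -1.17.

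The title also names proliferation. Genes of DNA replication rose: 19 of the 26 G1/S and DNA replication genes tested were higher in the libraries labelled knockout and none was lower, or 20 and 0 adjusted over the list alone, with a median log2 fold change of 0.41. CDC6, a replication licensing factor in the chromosome 17 block, rose from 44.2 ± 7.01 to 129.9 ± 6.39 CPM (SD, n = 4), and the transcription factor E2F1 from 21.7 ± 2.56 to 38.1 ± 3.93 CPM. The list was called by camera (adjusted p = 0.000250, and adjusted p = 0.553 with an estimated correlation). Without the block 18 of 25 rose (camera adjusted p = 5.53e-05, and adjusted p = 0.567 with an estimated correlation). The groups also differ in reads of the CDK inhibitor genes CDKN2A and CDKN2B, given below. A link of this rise to SMAD6 cannot be separated from that difference and was not tested. Of 26 mitotic genes, 5 rose and 1 fell, or 3 and 1 adjusted over the list alone, with a median of 0.01 and no camera call (adjusted p = 0.559). BIRC5, or survivin, rose by 1.04 and the topoisomerase TOP2A by 0.89 on the log2 scale, both in the block, without which 3 of 24 mitotic genes rose. The kinesin KIF20A fell by 0.25 (SE 0.07, edgeR adjusted p = 0.0133), with groups that overlapped. Its call ended against a minimum 1.2-fold change (edgeR adjusted p = 0.642) and with replicates 3 and 4 alone, a fit chosen after the data were seen, where its log2 fold change was -0.09 (edgeR adjusted p = 0.473). MKI67, the Ki-67 antigen, was 523 ± 72.1 and 581 ± 58.9 CPM (SD, n = 4), a log2 fold change of 0.15 (SE 0.10, edgeR adjusted p = 0.238, and 0.0162 with the replicate block).

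Genes that restrain the cell cycle included 2 with no read in the libraries labelled knockout. CDKN2A, which encodes p16 and ARF, had 101 reads over the wild-type libraries and none over the other 4, and CDKN2B, which encodes p15, had 275 and none. These are at least 7.66-fold and at least 20.9-fold lower, with a floor of 3 counts per library. MTAP, the coding gene next to CDKN2A, had 816 and 0 reads, while KLHL9 and DMRTA1 on either side had 13411 and 1763 reads in the libraries labelled knockout. Of 9 CDK inhibitors and pocket proteins, 4 fell and none rose (camera adjusted p = 0.0698, and adjusted p = 0.368 with an estimated correlation). The list was called without wild type replicate 1, 2 or 3 (camera adjusted p = 0.0330, 0.0367 and 0.0411), without replicate 3 or 4 labelled knockout (0.0170 and 0.0252) and with no low-count filter (0.00986). Its median log2 fold change was -0.18 and its mean -1.96. The neighbours CDKN2A and CDKN2B are 2 of the 4 falls, and the list was not tested without them. Targets of p53 fell, 15 of 20 with 1 rise. SPATA18, a mitophagy gene, fell from 13.0 ± 0.256 to 1.43 ± 0.178 CPM (SD, n = 4) and the stress cytokine GDF15 from 79.5 ± 2.72 to 27.8 ± 2.54 CPM, whereas the mitochondrial reductase FDXR, in the chromosome 17 block, rose by 0.62 on the log2 scale. This list was called by camera (adjusted p = 0.000250, and adjusted p = 0.285 with an estimated correlation). A link of its fall to SMAD6 was not tested either, since the groups also differ in CDKN2A and CDKN2B.

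**Figure D4:**
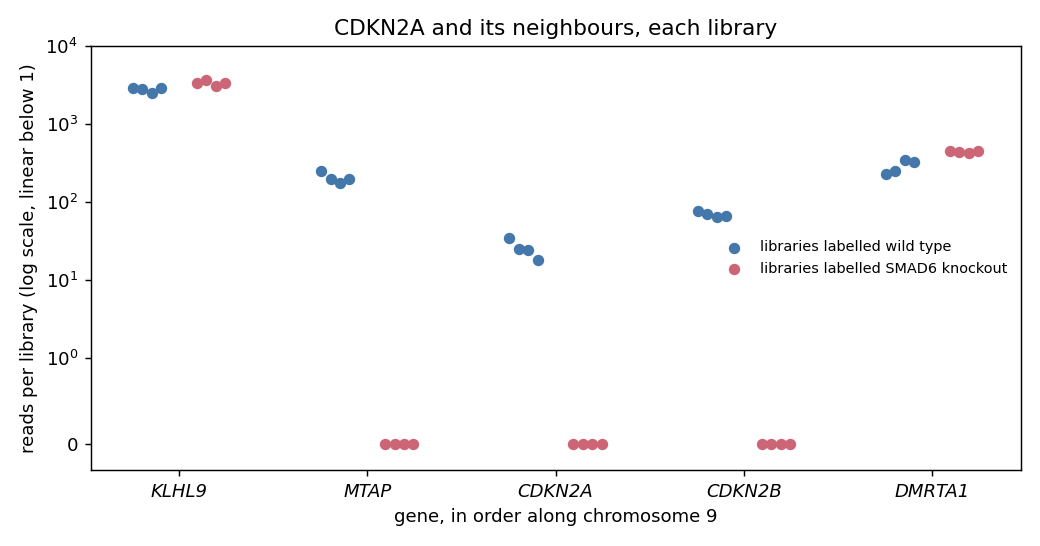
Reads per library (log axis, linear below 1) of CDKN2A and 4 genes near it, in their order along chromosome 9, blue for wild type and red for the libraries labelled SMAD6 knockout. MTAP, CDKN2A and CDKN2B had 816, 101 and 275 reads over the wild-type libraries and 0 over the others, while KLHL9 had 11056 and 13411.

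TGF-beta targets, matrix genes and mesenchymal regulators were lower. Of 18 TGF-beta target genes, 13 fell and 2 rose, with a median log2 fold change of -1.17 (camera adjusted p = 0.000596, and adjusted p = 0.117 with an estimated correlation). TAGLN, an actin-binding protein, fell from 38.2 ± 17.8 to 3.08 ± 0.806 CPM (SD, n = 4) and the ligand TGFB2 from 45.3 ± 11.7 to 5.97 ± 2.28 CPM. TGM2, a transglutaminase, rose by 0.33 on the log2 scale, a call that ended against a minimum 1.2-fold change (edgeR adjusted p = 0.153). Of 19 basement membrane and matrix genes, 12 fell and 1 rose (camera adjusted p = 0.00173, and adjusted p = 0.368 with an estimated correlation). COL5A1 fell by 2.22 and NID2, a basement membrane linker, fell by 2.96, while the laminin chain LAMA5 rose by 0.39, a call that ended against a minimum 1.2-fold change (edgeR adjusted p = 0.156). Of 8 transcription factors and markers of endothelial-to-mesenchymal transition, 7 fell and none rose (camera adjusted p = 0.00173, and adjusted p = 0.117 with an estimated correlation). TWIST2 fell from 5.95 ± 0.518 to 0.0587 ± 0.0513 CPM, and PRRX1 had 123 reads in wild type and none in the other group, at least 9.34-fold lower.

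Markers of other cell types moved beside these groups. Of 5 fibroblast markers tested, 3 fell and 1 rose (camera adjusted p = 0.0817, and adjusted p = 0.285 with an estimated correlation), with PI16 up by 4.05 on the log2 scale, COL1A2 silent in the libraries labelled knockout and COL6A3 at a log2 fold change of -2.15 (SE 0.24). The fibroblast list was called downwards by camera with no low-count filter (adjusted p = 0.00314) and by fry (adjusted p = 3.21e-07), which does not compare it with other genes. All 3 mural cell markers tested fell, and RGS5, a regulator of G protein signalling, fell by 1.99. Of 4 keratinocyte markers, 2 rose and 1 fell. The keratins KRT15 and KRT10, both in the chromosome 17 block, rose by 3.76 and 1.32, and PERP fell by 0.48. Of 3 melanocyte markers 1 rose, PMEL, from 0.270 ± 0.148 to 0.706 ± 0.113 CPM. Of 4 leukocyte markers 1 rose and 1 fell, with a median of -0.00468 and a mean of 0.45. CD14 rose from 0.0652 ± 0.0458 to 0.347 ± 0.0975 CPM, and LAPTM5 fell by 0.54. The last 4 lists had too few tested members for camera.

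Endothelial markers moved in both directions. The adhesion receptor CDH5, or VE-cadherin, remained abundant at 1285 ± 54.2 and 995 ± 57.1 CPM (SD, n = 4), a log2 fold change of -0.37. CLDN5, a tight junction protein, and ICAM2, in the chromosome 17 block, rose by 1.98 and 1.83, and the sialomucin EMCN fell by 4.33. Of 20 pan-endothelial markers, 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.231). Arterial markers fell: 11 of 14 were lower and 3 higher, with a median of -1.73 (camera adjusted p = 0.00282, and adjusted p = 0.168 with an estimated correlation). EFNB2, an ephrin ligand, and FBLN5 were among the 12 largest falls of genes with an average log2 CPM of at least 3 and no overlap between groups, but IGFBP3, a binding protein of insulin-like growth factors, rose from 155 ± 23.0 to 1275 ± 99.9 CPM and the kinase BMX rose by 1.52 on the log2 scale. Of 7 venous markers, 4 rose and 2 fell (camera adjusted p = 0.609), with ACKR1 and EPHB4 up by 1.90 and 0.64. The log2 fold changes of NT5E and FLRT2 were -1.65 and -1.23. The venous median was 0.51 and the mean 0.18, with camera pointing up and fry down. Of 9 lymphatic markers, 4 rose and 4 fell, or 5 and 4 adjusted over the list alone. PROX1, the lymphatic master regulator, fell by 4.34, FLT4 had the largest fall of the list, and MMRN1 and TFF3 rose by 1.68 and 0.47. The lymphatic median was 0.27, the mean was -1.55 and camera pointed down without a call (adjusted p = 0.773).

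Growth factor receptors of sprouting changed in opposite ways. KDR, the main VEGF receptor, fell from 589 ± 39.0 to 379.6 ± 21.3 CPM (SD, n = 4), a log2 fold change of -0.63, whereas FLT1, the decoy VEGF receptor, rose by 1.31 and the peptide APLN by 0.82. ANGPT1, the TEK ligand, had 281 reads in wild type and none in the other group, at least 21.3-fold lower. Of 22 tip cell and sprouting genes, 14 fell and 6 rose (camera adjusted p = 0.00686, and adjusted p = 0.285 with an estimated correlation). Of 18 junction genes, 6 rose and 8 fell, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.773), and JAM3, with 1421 reads in wild type, had none in the libraries labelled knockout. OCLN, or occludin, fell by 1.34, and the connexin GJC1, in the chromosome 17 block, rose by 1.21. Of 16 NOTCH pathway genes, 4 rose and 7 fell (camera adjusted p = 0.319); RFNG, a glycosyltransferase gene in the block, and the ligand DLL4 rose by 0.90 and 0.48, and HEY2 fell by 1.53. Flow-response genes rose, 8 of 12 with 1 fall (camera adjusted p = 0.00318, and adjusted p = 0.117 with an estimated correlation). KLF2, the flow-induced transcription factor, rose from 50.4 ± 4.67 to 144 ± 30.7 CPM (SD, n = 4), PTGS1, or cyclooxygenase 1, from 27.1 ± 3.77 to 231 ± 5.73 CPM, and ASS1 by 2.93 on the log2 scale, while PALMD fell by 0.56.

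Stress and inflammatory genes completed the fixed lists. Of 18 genes of the unfolded protein and amino acid stress responses, 10 rose and 1 fell. The chaperone HSPA5 rose from 1209 ± 94.0 to 2617 ± 46.9 CPM (SD, n = 4) and SDF2L1 by 1.37 on the log2 scale, whereas PHGDH, which starts serine synthesis, had 1168 reads in wild type and none in the other group, at least 88.7-fold lower. The list was called by camera (adjusted p = 0.0389, and adjusted p = 0.213 with an estimated correlation), its median was 0.31 and its mean -0.23, and the call was lost without replicate 1 or 2 labelled knockout (adjusted p = 0.0515 and 0.0510) and, in a fit chosen after the data were seen, with replicates 3 and 4 alone (0.0737). FOXO targets fell, 9 of 13 with 1 rise, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.285 with an estimated correlation). Among them IRS2 had 259 reads in wild type and none in the other group, at least 19.6-fold lower, and FBXO32 fell by 1.97, while KLF2 was the member that rose. Of 18 NF-kB and adhesion genes, 11 fell and 2 rose, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.0817, and adjusted p = 0.722 with an estimated correlation), and the cytokines IL1B and IL1A had log2 fold changes of -4.56 and -2.53. Both genes that rose, CSF3 and CCL2, lie in the chromosome 17 block, with rises of 0.63 and 0.96. The CCL2 call (edgeR adjusted p = 0.0320) was lost without wild type replicate 3 or 4 (0.0704 and 0.0819) and without replicate 1 or 2 labelled knockout (0.0814 and 0.0718). DESeq2 (adjusted p = 0.0635), no low-count filter (0.0604) and a minimum 1.2-fold change (0.0724) ended it too. The list was called without the chromosome 17 block (camera adjusted p = 0.0227, and adjusted p = 0.594 with an estimated correlation), with no low-count filter (0.0307) and without wild type replicate 3 or 4 (0.0341 and 0.0273).

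Of 18 interferon-stimulated genes, 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.161), and BST2, or tetherin, and IFI44L had log2 fold changes of -5.01 and -1.73. USP18, an interferon-induced protease, rose by 0.46, and OASL rose by 1.10 (edgeR adjusted p = 0.0353). The OASL call was lost without wild type replicate 1 or 4 (edgeR adjusted p = 0.0916 and 0.0955) and without replicate 2 or 3 labelled knockout (0.109 and 0.106). DESeq2 (adjusted p = 0.0732), no low-count filter (0.0567) and a minimum 1.2-fold change (0.0737) ended it too, as did replicates 1 and 2 alone (0.135) and replicates 3 and 4 alone (0.102), both chosen after the data were seen. Of 16 YAP-TEAD targets, 10 fell and 3 rose (camera adjusted p = 0.0927), with the kinase LATS2 and the adaptor AMOTL1 up by 0.91 and 0.51 and TGFB2 and NT5E the largest falls. Of 16 hypoxia and glycolysis genes, 3 rose and 4 fell (camera adjusted p = 0.885, upwards, against fry downwards). PFKFB4 and NDRG1 rose by 0.75 and 0.70, and VEGFA and the glucose transporter SLC2A3 had log2 fold changes of -0.90 and -0.32; the SLC2A3 call ended against a minimum 1.2-fold change (edgeR adjusted p = 0.214). Of 19 cholesterol synthesis genes, 5 rose and none fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.266), with STARD4 up by 0.62.

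Of 17 matrix proteases and inhibitors, 6 rose and 6 fell (camera adjusted p = 0.559); the median was -0.08 and the mean 0.33. The proteases ADAMTS18 and ADAMTS9 rose from 9.63 ± 1.25 to 269.8 ± 28.4 CPM and from 36.6 ± 2.55 to 219 ± 22.1 CPM (SD, n = 4), and MMP10 fell by 2.34. Of 9 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 5 rose and none fell, with H2BC5 and H1-2 up by 1.48 and 1.11. The histone list was called by camera (adjusted p = 0.0399, and adjusted p = 0.285 with an estimated correlation), and the call was lost with the replicate block (adjusted p = 0.0806) and without replicate 1 or 4 labelled knockout (0.0515 and 0.0569), and with replicates 1 and 2 alone (0.116), a fit chosen after the data were seen. In 23 of the 33 lists the counts of rises and falls were equal when adjusted over the list alone.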

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

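In 9 of 274 groups of 4 libraries examined, 1 library lay far from the other 3, where chance gives about 1 in 20. PLCB4 was 19.8 CPM in replicate 3 labelled knockout, against 23.7 CPM in the nearest of the others. E2F1 was 43.9 CPM in the same library, against 36.6 CPM in the nearest. KRT10 was 11.7 CPM in wild type replicate 1, against 9.88 CPM in the nearest. BMPR2 was 303 CPM in wild type replicate 4, against 263 CPM in the nearest. The other 5 were single libraries with a few reads of a gene that had none in the rest of its group: LPL at 0.0519 CPM and ATP6V0A4 at 0.0692 CPM in wild type replicate 3, DCLK1 at 0.104 CPM in wild type replicate 4, MIR217HG at 0.105 CPM in wild type replicate 2, and PTK7 at 0.0372 CPM in replicate 1 labelled knockout.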

How the results depend on the processing

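The fits without the chromosome 17 block, with replicates 1 and 2 alone and with replicates 3 and 4 alone were chosen after the data were seen. The count of 7228 changed genes lay between 6529 and 7326 without any single library and was 8377 with the replicate block, which changed no call of a named gene or list other than DUSP6, MKI67 and the histone list. Against a minimum 1.2-fold change it was 4072, with 1901 higher and 2171 lower, as that test asks for more than a difference. Genes changed at least 2-fold numbered 2069 on counts, 1007 on log2(TPM + 1) and 1316 on log2(TPM + 0.1), where 13209 genes were tested in place of 14960. On counts with a filter of 1 CPM in 4 or more libraries, 12766 genes were tested and 1439 had changed at least 2-fold. A stricter filter alone thus lowered the number. The 2 fits on TPM differ only in the value added before the log. What made the rest of the difference was not tested. Lists past the threshold went from 11 to 0 with an estimated correlation, where G1/S genes had adjusted p = 0.553, and to 24 with fry, which does not compare a list with other genes. With fry the BMP-SMAD targets passed downwards (adjusted p = 0.000142), and venous markers turned from up to down (adjusted p = 0.0408). Among 2894 values of 134 named genes, 2850 kept their direction and side of the threshold, 40 lost the call, 3 gained it and 1 changed direction without a call, BMPR2 at -0.00673 with replicates 1 and 2 alone. Of the 40, 10 came with the minimum 1.2-fold change, and ATF3, OASL, CCL2 and CCND1 lost their calls most often. Among 491 values of 29 lists, 438 kept theirs, 18 lost the call, 28 gained it and 7 changed direction, of which only the venous markers with fry had a call. The ERK list turned from down to up without replicate 3 or 4 labelled knockout (adjusted p = 0.931 and 0.940, in a range of 0.752 to 0.989 without any single library) and with replicates 1 and 2 alone (0.692). The hypoxia list turned from up to down with fry (adjusted p = 0.210) and with replicates 3 and 4 alone (0.979), and so did matrix proteases with replicates 3 and 4 alone (0.991); the cause was not tested. SMAD6 kept its direction and call, with a log2 fold change of 0.65 without replicate 3 labelled knockout and 0.99 with replicates 3 and 4 alone as the lowest and highest values. The count was 6647 without the chromosome 17 block, 7548 with replicates 1 and 2 alone and 5612 with replicates 3 and 4 alone, where ENG (adjusted p = 0.0537), KIF20A (0.473), OASL (0.102) and the unfolded protein list (0.0737) lost their calls and YAP-TEAD targets (0.0103) gained one. With replicates 1 and 2 alone ATF3 (adjusted p = 0.132), OASL (0.135) and the histone list (0.116) lost theirs, and MKI67 (0.0188) and the CDK inhibitor (0.0366), interferon (0.0262), NF-kB (0.000586) and cholesterol (0.0189) lists gained one. Tests with several deposited values per gene were not run, since each gene has 1. The main fit tested only the 14960 genes that the low-count filter kept, so a change in the genes it removed was not examined there. The floor of 3 counts per library served the fold bounds and is not a limit of detection.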

Other observations

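The tests of exchanged libraries, BMP-SMAD transcription, depth, chance runs of neighbours and fibroblasts were chosen after the result was seen. Genes silent in 1 group were counted among the tested genes. With a mean of 1 CPM or more in the other libraries, 49 genes had no read in the 4 libraries labelled knockout and 6 had none in the 4 wild-type libraries. The 4 libraries of a group were also parted into 2 and 2 in 6 ways. A gene silent in 2 and at that level in the other 2 was met 1 time within each group. The low-count filter asks for reads in at least 4 libraries, so it removed genes present in 2 libraries alone before this count. The counts within groups therefore cannot be set against those between groups.

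SMAD6 reads were more frequent in the libraries labelled SMAD6 knockout. An exchange of single libraries is argued against, since each of the 8 libraries correlated better with the rest of its own group, by at least 0.0571. Extra copies of a wide region around SMAD6 are argued against as well: the 20 nearest tested genes had a median log2 fold change of 0.13 (bootstrap 95% interval 0.01 to 0.42). Of these genes 7 were higher and 1 lower past the edgeR threshold. A median over them cannot speak on a short gain that holds SMAD6 and few neighbours. Higher BMP-SMAD transcription as a whole was not shown and stays open: of the target list 7 fell and 4 rose, camera pointed down with a p of 0.183, and fry, which does not compare a list with other genes, passed downwards (adjusted p = 0.000142). A knockout allele whose transcript is still made stays open as untested. Different starting cells in the 2 groups stay open too, but a check bears on them. The check for mixed-up samples found 4 of the 8 libraries unlike the other 4 and 0 unlike the rest of their own group. Its split thus followed the labels, as it would with different starting cells. The check cannot show how the difference arose.

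Read counts shifted over blocks of neighbouring genes in the libraries labelled SMAD6 knockout. Loss of a segment that reaches MTAP may account for the silent genes beside CDKN2A, as MTAP had 0 reads in the 4 libraries. CDKN2B-AS1, between CDKN2A and CDKN2B in gene order, had 30 reads in wild type and 1 in the libraries labelled knockout. Lower depth is argued against, since total counts differed by a ratio of 1.09. A chance run on chromosome 17 is argued against, since the highest median of 15 neighbours was 1.25 there and 1.02 over 1000 shuffles of gene order. Extra copies of the long arm of chromosome 17 may account for that run, where the more and less expressed genes differed in median by 0.0202 on the log2 scale. These values are ratios between the groups, so they cannot tell a gain in the libraries labelled knockout from fewer copies in wild type. Whether such changes arose with the knockout, in culture or in different starting cells was not tested.

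Most TGF-beta target and matrix genes were lower in the libraries labelled SMAD6 knockout, 13 of 18 with 2 rises and 12 of 19 with 1 rise. With an estimated correlation camera called neither list (adjusted p = 0.117 and 0.368). Fibroblasts mixed into the wild-type cultures are argued against: COL3A1, LUM and DCN together reached 0.00367 of the CPM of COL1A2, with 30, 25 and 16 reads over the 4 wild-type libraries. No biological explanation was tested, and a link to SMAD6 stays open as untested, since the groups also differ in the blocks above.

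If the pairing of replicate numbers is left aside, no other split reached the count of genes, while other splits reached the count of lists. If the pairing is kept, the splits cannot exclude chance for either count. Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, called as many as 7228 genes, and the highest other split called 0. Every other split puts libraries of both groups in each arm, which adds to the spread within arms. Only 8 splits part all 4 pairs of same-numbered libraries, too few for a share under 0.05, with 7228 genes in the real one and 0 as the highest of the others. For the 11 lists, 3 of the 35 splits gave as many. The others exchange replicate 3 labelled knockout for wild type replicate 3, with 14 lists and all 4 pairs parted, or for wild type replicate 2, with 11 lists. Both called 0 genes.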
